A study of Mus musculus with 10 samples.

How the data were processed

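RNA sequencing was carried out on Neuro2a cells, a mouse neuroblastoma line. Cells carried 1 of 4 kinds of plasmid: dCas9 directed at SCN9A, called dCas9-SCN9A (3 libraries), its control dCas9-empty (3 libraries), a zinc-finger protein directed at SCN9A, called ZF-SCN9A (2 libraries), or mCherry, a red fluorescent protein taken here as its control (2 libraries). dCas9 is a Cas9 that no longer cleaves DNA, and a zinc-finger protein is an engineered DNA-binding protein. Per the labels' protocols, cells were transfected with Lipofectamine, RNA was purified on RNeasy columns, libraries were made with a NEBNext Ultra II kit, and sequencing ran on an Illumina NovaSeq. What dCas9-empty lacks, and the position at which either repressor binds, are not given in the sources used here.

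The deposited values are raw read counts per gene for each library, unnormalised, in the layout of STAR's gene counts, with 1 unstranded and 2 stranded columns. Per the submitters' processing notes, bcl2fastq 2.20, STAR 2.7.3a and DESeq2 were used with the mouse build GRCm38. The authors' annotation release, read trimming and counting settings are not given in the sources used here. The 2 strand columns held about equal numbers of reads, so the unstranded column was used for all results. Reads of a gene and of a gene overlapping it on the other strand therefore cannot be told apart, and reads shared by near-identical copies, which include nuclear copies of the mitochondrial genome, leave those genes uncertain. Each file lists 55401 gene identifiers, of which 55141 were found in the GENCODE M21 annotation of GRCm38 and 260 had no symbol. Gene coordinates are those of that annotation.

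The 4 entries that name no gene (unmapped, multimapping, outside genes, ambiguous) held 26.1% of listed reads in dCas9-empty, 27.9% in dCas9-SCN9A, 25.8% in mCherry and 27.8% in ZF-SCN9A on average. They were kept out of library sizes and tests, as were 4 plasmid entries named mCherry, ZF, dCCas9 and dNCas9. Depth is given as the sum of gene counts. All pairs of replicates differed by more than sampling noise in a chi-square test over genes, so no library was counted as a copy of another. The labels do not say that replicates came from separate cultures. P-values therefore measure only the spread between these samples, which may be technical.

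The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the counts, with TMM scaling, edgeR's filter on low counts by group, robust fitting and two-sided p-values. Adjusted p-values are from this test with Benjamini-Hochberg adjustment unless another tool is named, and genes with an adjusted p under 0.05 are called changed. Each repressor was compared with its own control in its own fit, with 4 residual degrees of freedom for dCas9 and 2 for ZF. The prior degrees of freedom, by which the fit borrows spread across genes, had a median of 13.0 for dCas9. For ZF they were infinite for 88.0% of genes. The p-values of those genes rest on spread shared across genes, not on their own. The difference between the repressors was tested as the contrast of both changes over all 10 libraries. The biological coefficient of variation was 6.07% in the dCas9 fit and 5.12% in the ZF fit. CPM values are counts scaled by the TMM-adjusted sum of gene counts (edgeR's cpm), and M stands for 1e6. Log2 fold changes carry the standard error of the fit, and the 95% interval of the Scn9a level comes from that fit. Scn9a was also put to an exact permutation test of log2 CPM without a prior count.

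Gene lists (27) were tested with limma's camera at a preset correlation of 0.01 and adjusted over the lists. Camera with an estimated correlation and limma's fry were run beside it. With an estimated correlation, camera rests on the residual degrees of freedom, 4 for dCas9 and 2 for ZF. Its lowest adjusted p over the 27 lists was 0.939 with dCas9 and 0.643 with ZF. A miss in that variant therefore cannot decide whether a list moved. The preset p-values have a limit too. The estimated correlation was 0.498 for the mitochondrially encoded messenger RNAs with dCas9. With the zinc finger it was 0.503 for hypoxia and glycolysis, 0.509 for ribosomal proteins, 0.253 for cholesterol and -0.017 for the ATF4 list. Where the estimate lies well above the preset 0.01, the preset p-value can be far too small. The lists cover sodium channels other than Scn9a, the neighbours of Scn9a, potassium and calcium channels, pain and opioid genes, interferon-stimulated genes, NF-kB targets, endoplasmic reticulum stress, the ATF4 and amino acid response, heat shock, p53 targets, DNA replication, mitosis, cholesterol synthesis, hypoxia and glycolysis, ribosomal proteins, nuclear-encoded respiratory chain subunits, mitochondrially encoded messenger RNAs, histones, immediate early genes, neuronal structure, sympathoadrenal identity, TRIM28 and its partners, lysosome and autophagy, NRF2 targets, and markers of fibroblasts, glia, and immune and endothelial cells. The lists, the tests, the rule for named genes and the alternative settings were chosen before the data were examined, with exceptions given here and in the closing section.

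Named genes follow a rule. Scn9a and the tested sodium channels and neighbours always count, and some genes that the rule or the lists would name are not reported here. Then come, per comparison, the 12 largest increases and 12 largest decreases among called genes with a mean of at least 5 CPM in the higher group and non-overlapping libraries. Where fewer than 5 pass, genes of smallest p fill up to 5 and are said not to pass. Added to these are up to 4 members of each called list, 6 genes per direction from the test of the difference, and up to 8 per direction called in both comparisons. Predicted genes, clone names, pseudogenes, identifiers without a symbol and duplicated symbols were left out of the largest changes, a slightly wider exclusion than first written. 1600002K03Rik was named by the last part of the rule. Gm45833, Gm44386, Gm2314, Dnmt3a, Fn1 and further list members named in the text fall outside the rule and were chosen after their values were seen.

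Each tool was tested on simulated counts with 50 genes changed at each of 4 fold sizes, drawn with the real means, library sizes and fitted dispersions. In the dCas9 design (14437 genes), edgeR recovered 56% of 1.25-fold, 80% of 1.5-fold, 82% of 2-fold and 96% of 4-fold changes, and 8.72% of its 172 calls were false. In the ZF design (12696 genes) it recovered 24%, 62%, 80% and 96%, and 5.07% of 138 calls were false. The simulated genes varied independently, with no trend by exon length and no structure shared between libraries. Many changed genes also ease the adjusted threshold. Recovery in the real data can therefore be lower, above all where few genes are called. Further simulated counts carried a trend with exon length and a 1.3-fold rise of the cholesterol list. Camera at the preset correlation called that list, but also 4 other lists in the dCas9 design and 3 in the ZF design. The alternatives were DESeq2 1.42.0, limma-voom, DESeq2's size factors or plain library size for scaling, no filter, a filter at a mean of 1 CPM, the strand column with more reads, all 10 libraries in 1 fit, the replicate number as a block, a 2-fold minimum, and each library left out in turn. A correction of each library for a trend with exon length or with GC content (lowess, span 0.3) was added after the data had been seen. An adjusted p that DESeq2 gave as missing was kept missing. Leaving out a ZF-SCN9A or mCherry library leaves a lone sample, which is then assumed to vary like the other group. Tables were handled with Python 3.11.15 and pandas 2.3.3, and figures drawn with matplotlib 3.10.9. Sites in the genome that resemble the repressors' targets were not analysed here.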

Results

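Gene expression was measured by RNA sequencing in Neuro2a cells carrying a repressor directed at SCN9A or its control plasmid. The dCas9 arm held 3 dCas9-SCN9A and 3 dCas9-empty libraries, and the zinc-finger arm 2 ZF-SCN9A and 2 mCherry libraries. The arms shared no library. The dCas9-empty libraries held 17.9 M, 19 M and 17.8 M gene counts (replicates 1 to 3), and the dCas9-SCN9A libraries 15.4 M, 16.4 M and 15.5 M. The zinc-finger arm was shallower, with 6.59 M and 7.48 M in mCherry and 6.30 M and 4.41 M in ZF-SCN9A. On average 23530 genes were detected per dCas9-empty library, 23580 in dCas9-SCN9A, 20647 in mCherry and 19984.5 in ZF-SCN9A.

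The first question was whether each repressor lowered its target in these cells. Scn9a (ENSMUSG00000075316) encodes the voltage-gated sodium channel NaV1.7, which carries pain signals in sensory neurons. It lies on the minus strand of chromosome 2 from 66480080 to 66634962 in GRCm38. In the dCas9-empty libraries it stood at 75.3, 81.1 and 78.3 CPM, and in the dCas9-SCN9A libraries at 31.0, 30.8 and 28.2 CPM. It stood at 62.4 and 56.3 CPM with mCherry, and at 18.8 and 15.7 CPM with ZF-SCN9A. With dCas9 it fell from 78.2 ± 2.91 to 30.0 ± 1.56 CPM (SD, n = 3 each), to 38.4% of control with a 95% interval of 35.1% to 42.0%. The log2 fold change was -1.38 ± 0.07 (SE), with an adjusted p = 2.24e-09 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the smallest p of the comparison. With the zinc finger it fell from 59.4 ± 4.27 to 17.3 ± 2.25 CPM (SD, n = 2 each), to 29.5% of control (24.5% to 35.5%). That log2 fold change was -1.76 ± 0.14 (SE, adjusted p = 1.71e-34). An exact two-sided permutation test of log2 CPM gave p = 0.1 over 20 permutations with dCas9 and p = 0.33 over 6 with the zinc finger, the smallest values these designs allow. The change with dCas9 minus that with the zinc finger was 0.39 ± 0.15 (SE, 95% interval 0.10 to 0.67), which did not pass adjustment over all genes (adjusted p = 0.278). Exons of the antisense gene Gm13629 overlap 1.41% of Scn9a's exon bases, and the counting did not separate strands.

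**Figure D1:**
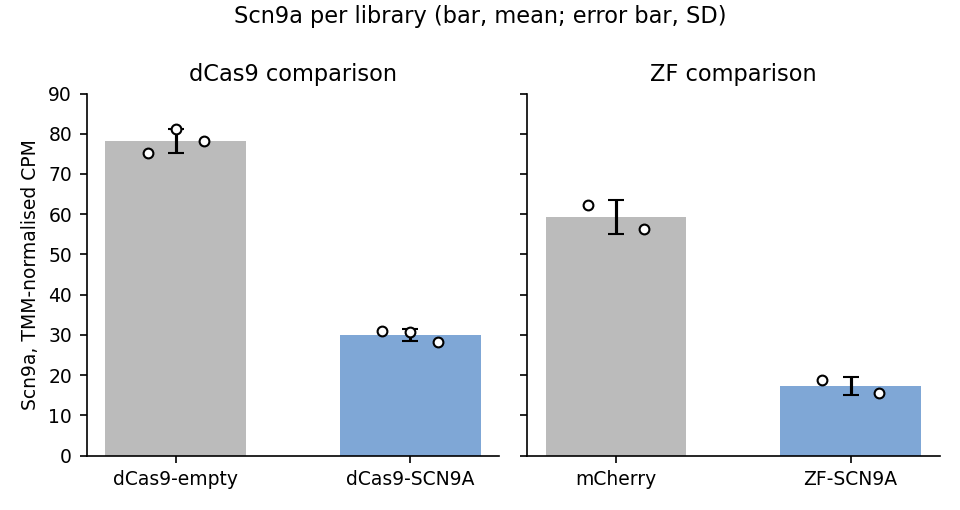
Scn9a level in CPM in each of the 10 libraries (points) with group means and SD (bars and error bars). The dCas9-SCN9A libraries lie between 28.2 and 31.0 CPM and the ZF-SCN9A libraries at 18.8 and 15.7 CPM, below every control library of their arm.

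The dCas9 comparison asked what else changed when dCas9 was directed at SCN9A. Scn9a had the only decrease that passed the main edgeR test, though 178 decreases passed with the replicate number as a block. Genes that rose were 1600002K03Rik, a short protein-coding gene on chromosome 10 (80172944 to 80175146), from 9.24 ± 1.51 to 18 ± 2.37 CPM (SD, n = 3 each), and Snora17, a small nucleolar RNA of the kind that guides pseudouridylation, from 2.92 ± 0.452 to 7.99 ± 2.33 CPM. mt-Co3, a cytochrome c oxidase subunit encoded in the mitochondrial genome, rose from 14.3 ± 1.84 to 23.4 ± 3.50 CPM. The long noncoding RNAs Gm45833 and Gm44386 also passed, with log2 fold changes of 0.75 (adjusted p = 0.00955) and 1.54 (adjusted p = 0.0455). For 1600002K03Rik, Snora17 and mt-Co3 the log2 fold changes were 0.96 ± 0.13, 1.45 ± 0.21 and 0.71 ± 0.12 (SE), with adjusted p = 0.00698, adjusted p = 0.00955 and adjusted p = 0.0498.

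In all, 6 of 14628 tested genes passed in the dCas9 comparison, 5 higher and 1 lower, and 3 of them changed at least 2-fold. At an unadjusted p under 0.05 there were 1476 genes, 610 higher and 866 lower. DESeq2 called 69 genes, 2 higher and 67 lower, sharing Scn9a alone with edgeR and giving no adjusted p for the other 5 edgeR calls, and limma-voom called 4. In all 6 called genes the libraries of both groups did not overlap, which held for 15.6% of all genes and is reached by chance in 10%. The genes of next smallest p did not pass: F12, coagulation factor XII, at 0.82 (adjusted p = 0.0624), the zinc transporter Slc39a7 at 0.79 (adjusted p = 0.148, 80.7% of its exon bases shared with Gm20427) and the ubiquitin ligase Rnf25 at 0.42 (adjusted p = 0.156). On the lower side, the engulfment receptor Megf10 stood at -0.46 (adjusted p = 0.0813), Tnrc6b, which acts in microRNA silencing, at -0.32 (adjusted p = 0.0906), the transcription factor Tcf4 at -0.33 and the aminopeptidase Lnpep at -0.29 (both with adjusted p = 0.0958).

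Every call in the dCas9 comparison other than Scn9a was lost without at least 1 library, though the log2 fold changes stayed near their size. Without dCas9-SCN9A replicate 3 all 5 were lost and 1 gene remained called, with 1600002K03Rik at an adjusted p = 0.0908. Gm45833 and Snora17 were also lost without dCas9-empty replicate 2 (highest adjusted p = 0.0973 for both), Gm44386 without dCas9-empty replicate 1 or 2 (highest adjusted p = 0.427), and mt-Co3 without dCas9-empty replicate 1 or 2 or dCas9-SCN9A replicate 1 (highest adjusted p = 0.402). In the fits that ended a call they were 0.85 for 1600002K03Rik, 0.67 to 0.72 for Gm45833, 1.21 to 1.39 for Snora17, 1.28 to 1.63 for Gm44386 and 0.61 to 0.75 for mt-Co3. The number and balance of calls also moved, to 1 higher and 2 lower without dCas9-empty replicate 2, 20 and 1 without dCas9-empty replicate 3, 4 and 30 without dCas9-SCN9A replicate 1, and 15 and 2 without dCas9-SCN9A replicate 2. Without a filter there were 56 higher and 116 lower, and with all 10 libraries 7 and 22. With the replicate number as a block there were 84 and 178, so the excess of increases is not firm. After a correction for exon length, 2 genes were called, Scn9a and Gm45833. The calls of mt-Co3 and Gm44386 also ended with plain library size, with the filter at 1 CPM and with limma-voom, that of mt-Co3 with DESeq2's size factors and that of Gm44386 with the strand column. Log2 fold changes fell with exon length across genes (Spearman -0.35, genes not being independent replicates). Of 5 equal groups of genes by exon length, the longest held 574 that were lower and 44 higher at an unadjusted p under 0.05, and the shortest 21 and 253.

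**Figure D2:**
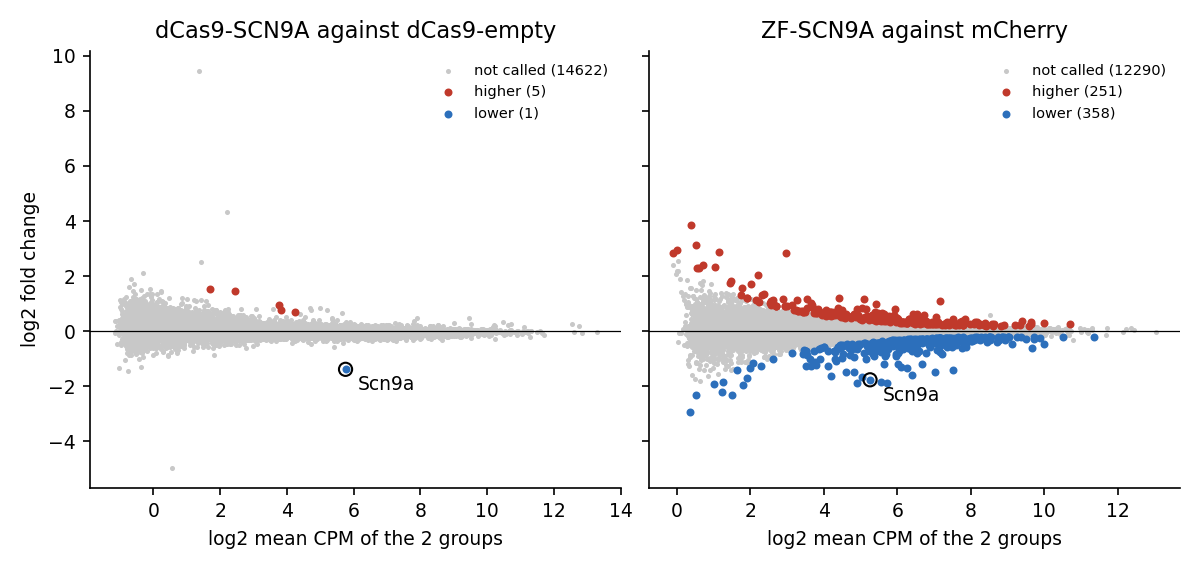
Log2 fold change of each tested gene (y axis) against its mean level in log2 CPM (x axis) for dCas9-SCN9A against dCas9-empty and ZF-SCN9A against mCherry, with called genes coloured. In the dCas9 panel 6 genes are called and Scn9a stands at -1.38, while the topmost point is Gm2314, at 0 in the dCas9-empty libraries. In the ZF panel 609 genes are called.

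Among the 13 messenger RNAs of the mitochondrial genome, which encode subunits of the respiratory chain, all had positive log2 fold changes with dCas9-SCN9A (median 0.33). The list was called higher by camera (adjusted p = 3.79e-12), but with an adjusted p = 0.939 with an estimated correlation. At the preset correlation, divisions of the same libraries that mix the groups gave 4 to 9 called lists, against 1 for the real division. A camera call at this setting can therefore arise without the repressor. mt-Co3 passed over all genes, and adjusted over the list alone 5 members passed, among them mt-Co2 (0.85 ± 0.15), mt-Atp8 (0.69 ± 0.18) and mt-Atp6 (0.54 ± 0.16, SE). These named members stood at means of 3.61 to 22.8 CPM in dCas9-empty, and reads shared with nuclear copies of the mitochondrial genome leave them uncertain. Multimapping reads were 8.21% of listed reads in dCas9-empty and 8.88% in dCas9-SCN9A. Their part in these changes was not tested. The mitochondrial share of gene counts was 1.94% ± 0.44 in dCas9-empty, lowest at 1.52% in replicate 1, and 2.33% ± 0.17 in dCas9-SCN9A (SD, n = 3 each). The list's median was 0.19 without dCas9-empty replicate 1, 0.55 without dCas9-empty replicate 3 and 0.19 after the correction for exon length, and camera called the list in each of these settings.

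Neighbouring and related channel genes were examined next. Of 8 other sodium channel genes tested, among them Scn1a, Scn2a, Scn3a and Scn8a, edgeR called 0 with dCas9, with log2 fold changes from -0.22 to 0.36. At an unadjusted p under 0.05 there was 1, Scn3a at -0.22 ± 0.08 (SE), and DESeq2, which gave an adjusted p for Scn8a and Scn3b alone, and limma-voom called 0. The 11 tested genes around Scn9a on chromosome 2 (Scn3a, Scn2a, Csrnp3, Galnt3, Ttc21b, Scn1a, Scn7a, B3galt1, Stk39, Cobll1 and Grb14) included 0 called by edgeR, 0 adjusted over the list alone, and 0 by limma-voom. DESeq2 called none of the 4 to which it gave an adjusted p (Galnt3, Ttc21b, B3galt1 and Stk39) and could call none of the other 7. Among them 3 had an unadjusted p under 0.05, Scn3a, Csrnp3 at -0.17 and B3galt1 at -0.15. Camera gave an adjusted p = 0.156 for the neighbours and an adjusted p = 0.797 for the sodium channels, while fry's test of change in either direction gave an adjusted p = 0.0334 for the neighbours, the 1 list of 27 to pass it with dCas9.

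The other 26 lists held 484 tested genes in the dCas9 comparison. None of these genes was called by edgeR, 38 had an unadjusted p under 0.05, DESeq2 called 2 (the DNA methyltransferase Dnmt3a at -0.24 and fibronectin, Fn1, at -0.17), giving no adjusted p for part of them, and limma-voom 0. Genes that passed adjusted over the list alone included Atf3, a stress-induced transcription factor (0.51), and Dnmt3a. Camera called 0 of these lists, with adjusted p from 0.156 to 0.976. The lists included NRF2 targets, p53 targets, interferon-stimulated genes and the markers of fibroblasts, glia, and immune and endothelial cells. In the hypoxia and glycolysis list 24 of 28 members were negative (median -0.057, adjusted p = 0.156). The sodium channel, pain and opioid, and neuronal structure lists had medians and means above 0 but a camera direction of lower, and the glia markers had a median below 0 and a mean above it.

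The ZF comparison asked the same of the zinc finger. Klhl7, an adaptor of a cullin ubiquitin ligase, fell from 82.9 ± 1.29 to 22.1 ± 1.15 CPM (SD, n = 2 each), a log2 fold change of -1.90 ± 0.12 (SE, adjusted p = 1.65e-50). Git1, a GTPase-activating protein for ARF GTPases, fell from 192 to 70.0 CPM (-1.48 ± 0.08, adjusted p = 4.43e-65), Ttbk1, a tau tubulin kinase, from 127 to 42.6 CPM (-1.59 ± 0.10, adjusted p = 9.08e-56) and Adam15, a membrane-bound metalloproteinase, from 73.4 to 20.6 CPM (-1.84 ± 0.13, adjusted p = 7.09e-44). Adm, which encodes the vasodilator peptide adrenomedullin, rose from 12.9 ± 4.12 to 29.6 ± 3.08 CPM (1.20 ± 0.17, adjusted p = 1.70e-10). Mamdc2 rose from 20.9 ± 0.573 to 47.8 ± 2.96 CPM (1.19 ± 0.14, adjusted p = 1.97e-15), and Ttll13, of a family that adds glutamate chains to tubulin, from 1.78 to 7.47 CPM (2.05 ± 0.38, adjusted p = 8.96e-06).

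Further large decreases with the zinc finger were those of the LIM-domain scaffold Limd1 (-1.86), the cap-binding protein Eif4e3 (-1.66), the sugar transporter Slc50a1 (-1.63), the threonyl-tRNA synthetase paralog Tarsl2 (-1.48), gamma-synuclein, Sncg (-1.47), the collagen galactosyltransferase Colgalt2 (-1.94) and Osgin1 (-1.68). The first 5 had adjusted p from 1.95e-30 to 1.20e-15, and the last 2 adjusted p = 9.18e-04 and adjusted p = 0.00251. Further increases were those of the glutamate transporter Slc1a7 (1.36), the galectin Lgals4 (1.3), Fgf11 (1.22), the RNA-binding protein Rbpms2 (1.22), Tmem8b (1.15), the hypoxia-induced Ankrd37 (1.14), the transcription factor Scrt2 (1.12), the glutamine transporter Slc38a3 (1.11) and the collagen chaperone Serpinh1 (1.11), with adjusted p from 2.00e-04 to 0.0491. On the opposite strand, 4731419I09Rik overlaps 20.6% of the exon bases of Adam15 and Lrp2bp and Ufsp2 overlap 22.7% and 3.70% of those of Ankrd37, and Gm20696 on the same strand 14.8% of those of Eif4e3.

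Across the ZF comparison 609 of 12899 tested genes were called, 251 higher and 358 lower, with a median size of 0.42 on the log2 scale. For 88.0% of genes this fit used only spread shared across genes. The count is therefore not like for like with the 6 of the dCas9 comparison. At least 2-fold changes numbered 70, 33 higher and 37 lower. Libraries of both groups did not overlap in 99.2% of called genes and in 45.6% of all genes, against 33.3% by chance. DESeq2 called 115 genes, 21 higher and 94 lower, all shared with edgeR, and limma-voom called 617. Among the 12 largest increases DESeq2 called Ttll13, Adm and Mamdc2, gave no adjusted p for Fgf11 and Rbpms2, and did not call the other 7. It gave none for Colgalt2 and Osgin1 either. The number of edgeR calls was 262 without mCherry replicate 1, 201 without ZF-SCN9A replicate 1 and 249 without ZF-SCN9A replicate 2. Log2 fold changes fell with exon length here too (Spearman -0.12), and 585 genes were called after a correction for it.

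Several calls among the largest ZF changes ended when a library was left out, which leaves a lone sample in its group, while every log2 fold change kept its direction. The calls of Fgf11 and Rbpms2 ended without any 1 of the 4 libraries (highest adjusted p = 0.550 and adjusted p = 0.345). Those of Slc38a3 and Serpinh1 ended without mCherry replicate 1 or either ZF-SCN9A replicate (adjusted p = 0.308 and adjusted p = 0.449), and those of Lgals4 and Scrt2 without mCherry replicate 2 or either ZF-SCN9A replicate (adjusted p = 0.139 and adjusted p = 0.130). The call of Slc1a7 ended without mCherry replicate 1 or ZF-SCN9A replicate 2 (adjusted p = 0.265), that of Tmem8b without ZF-SCN9A replicate 1 (adjusted p = 0.129), and those of Colgalt2 and Osgin1 without mCherry replicate 1 or ZF-SCN9A replicate 1 (adjusted p = 0.291 and adjusted p = 0.172). In these fits the log2 fold changes were 0.98 to 1.43 for Fgf11, 0.92 to 1.57 for Rbpms2, 0.79 to 1.20 for Slc38a3, 1.08 to 1.42 for Lgals4, 0.91 to 1.17 for Scrt2, 1.09 for Tmem8b and -1.59 to -1.48 for Osgin1. Larger moves were those of Serpinh1 (0.66 without mCherry replicate 1 and 1.85 without mCherry replicate 2), Slc1a7 (0.91 and 2.12 without the same libraries) and Colgalt2 (-1.26 without ZF-SCN9A replicate 1 and -2.76 without ZF-SCN9A replicate 2). Klhl7, Limd1, Adam15, Eif4e3, Slc50a1, Ttbk1, Tarsl2, Git1, Sncg, Ttll13, Adm, Mamdc2 and Ankrd37 stayed called without each library. With the strand column the calls of Ttll13 (1.27, adjusted p = 0.284), Rbpms2 (0.49, adjusted p = 0.796) and Slc38a3 (0.73, adjusted p = 0.508) ended, as did those of Lgals4, Fgf11, Scrt2 and Serpinh1, and Osgin1 stood at -2.55. With all 10 libraries in 1 fit the calls of Adm (1.19, adjusted p = 0.172), Fgf11, Rbpms2 and Serpinh1 ended. Those of Fgf11 and Rbpms2 also ended without a filter and with the replicate number as a block. That of Fgf11 ended with limma-voom, and that of Rbpms2 with the filter at 1 CPM and after the correction for exon length.

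The cholesterol synthesis list was called lower by camera with the zinc finger (adjusted p = 2.02e-08), but with an adjusted p = 0.643 with an estimated correlation and an adjusted p = 0.115 by fry. Divisions of these libraries that mix the groups gave 3 and 1 lists called by camera, against 4 for the real division. Of the tested cholesterol genes 24 of 24 were negative (median -0.21), 4 were called lower over all genes and 11 adjusted over the list alone. The 4 were the synthesis enzymes Hmgcs1 (-0.35 ± 0.07), Lss (-0.31 ± 0.07), Sqle (-0.29 ± 0.07) and Cyp51 (-0.29 ± 0.07, SE, n = 2 each). The ATF4 and amino acid response list was called higher by camera (adjusted p = 1.05e-05, but adjusted p = 0.643 with an estimated correlation). That rise in p does not come from the correlation, estimated at -0.017, below the preset 0.01, for this list. Of its 24 members 22 were positive and 6 were called higher, 7 adjusted over the list alone: the pseudokinase Trib3 (0.43 ± 0.07), the mTORC1 inhibitor Ddit4 (0.28), stanniocalcin Stc2 (0.42), the translation repressor Eif4ebp1 (0.25), Atf3 (0.51) and the proline synthesis enzyme Pycr1 (0.35). The call of Hmgcs1 and of Cyp51 ended without ZF-SCN9A replicate 1 (adjusted p = 0.135 and adjusted p = 0.242), that of Sqle without ZF-SCN9A replicate 2 (adjusted p = 0.302) and that of Lss without mCherry replicate 2 or ZF-SCN9A replicate 1 (highest adjusted p = 0.189). Ddit4 and Stc2 lost theirs without mCherry replicate 1 or ZF-SCN9A replicate 1 (adjusted p = 0.427 and adjusted p = 0.229), Pycr1 without mCherry replicate 1 or ZF-SCN9A replicate 2 (adjusted p = 0.698), and Eif4ebp1 and Atf3 without mCherry replicate 1 or either ZF-SCN9A replicate (adjusted p = 0.185 and adjusted p = 0.153). Without mCherry replicate 1 the log2 fold change of Ddit4 was 0.15 and that of Pycr1 0.15, without mCherry replicate 2 they were 0.42 and 0.60, and without ZF-SCN9A replicate 2 that of Pycr1 was 0.20. Calls also ended with the strand column for Eif4ebp1, Atf3 and Pycr1, and with all 10 libraries in 1 fit for Ddit4 and Pycr1. That of Ddit4 ended with the replicate number as a block, and that of Pycr1 without a filter. Of the 10 genes named here, DESeq2 called Hmgcs1 and Trib3.

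The hypoxia and glycolysis list was also called higher by camera with the zinc finger (24 of 28 positive, median 0.098, camera adjusted p = 6.30e-05, but adjusted p = 0.643 with an estimated correlation). Adm, Ankrd37, Ndrg1 (0.63), hexokinase Hk2 (0.38), the pyruvate dehydrogenase kinase Pdk1 (0.43) and the glucose transporter Slc2a3 (0.36) were called higher, and the glycolytic enzyme Tpi1 fell (-0.62 ± 0.06, adjusted p = 9.05e-21). Adjusted over the list alone 10 were higher and 1 lower. The list's call depended on mCherry replicate 1, without which the median was -0.012 (adjusted p = 0.848), and without mCherry replicate 2 the median was 0.25. Hk2 and Slc2a3 lost their calls without mCherry replicate 1 (adjusted p = 0.0765 and adjusted p = 0.371), Pdk1 without mCherry replicate 1 or ZF-SCN9A replicate 2 (adjusted p = 0.247) and Ndrg1 without ZF-SCN9A replicate 1 (adjusted p = 0.152). Without mCherry replicate 1 the log2 fold changes were 0.24 for Hk2, 0.15 for Slc2a3 and 0.28 for Pdk1, and without mCherry replicate 2 that of Slc2a3 was 0.60. With all 10 libraries in 1 fit the calls of Adm, Ndrg1, Hk2, Pdk1, Slc2a3 and Tpi1 ended, the last at -0.62 (adjusted p = 0.190). Those of Pdk1 and Slc2a3 also ended with the strand column, and that of Slc2a3 with limma-voom, with the replicate number as a block and after the GC correction. DESeq2 called Adm and Tpi1 of these genes. Ribosomal protein genes, which are short, were positive in 28 of 30 cases (median 0.10, camera adjusted p = 6.82e-05, but adjusted p = 0.643 with an estimated correlation). Rplp1 alone was called (0.25 ± 0.06, SE), a call lost without mCherry replicate 1 or either ZF-SCN9A replicate (highest adjusted p = 0.359) and with all 10 libraries, DESeq2 or the correction for exon length, and 2 members passed adjusted over the list alone. Values for Rpl19 (0.19), Rpl13 (0.15) and Rps23 (0.15) did not pass. Without mCherry replicate 2, Rpl13 (0.25, adjusted p = 0.0115) and Rps23 (0.23, adjusted p = 0.0237) passed, and without mCherry replicate 1 they stood at 0.057 and 0.076.

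**Figure D3:**
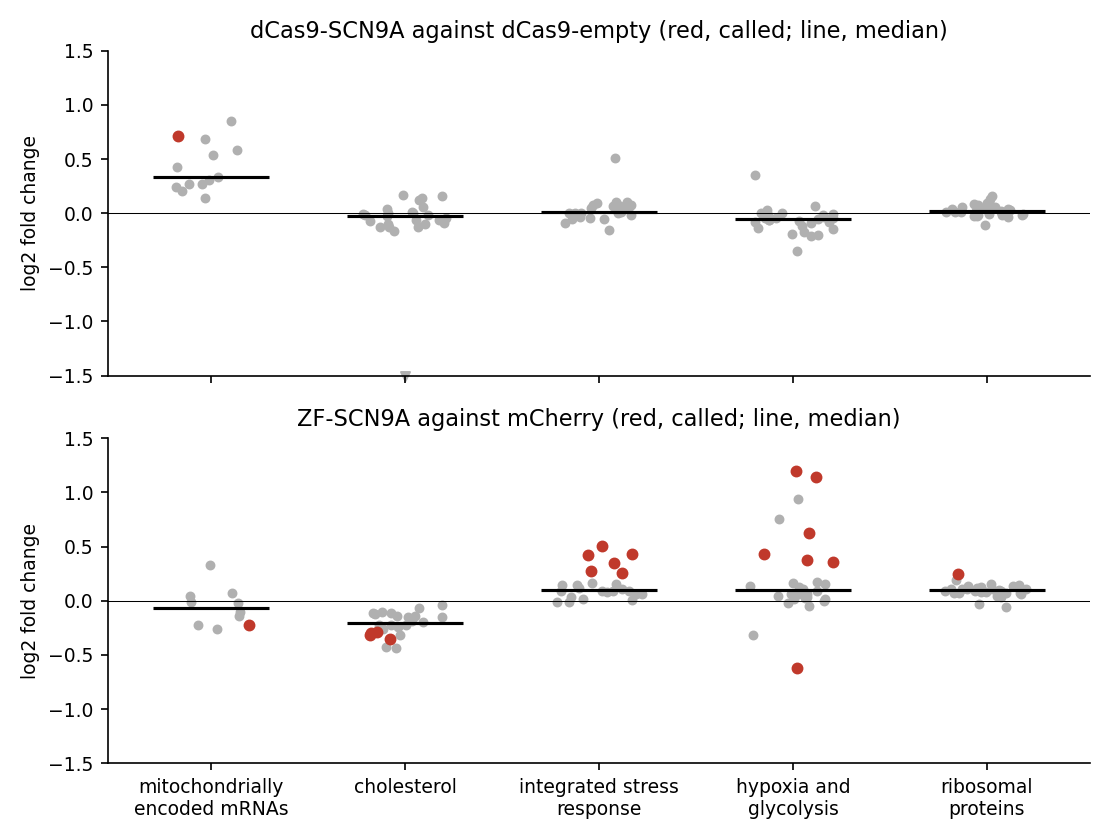
Log2 fold change (y axis) of each tested member (points) of the called lists in the dCas9 and ZF comparisons, with called members in red, the median as a line and a triangle for a value below the axis. The 13 mitochondrially encoded messenger RNAs lie above 0 with dCas9 (median 0.33), and the 24 cholesterol genes below 0 with the zinc finger (median -0.21).

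Sodium channel genes other than Scn9a were also tested with the zinc finger. Scn3a, a neighbour of Scn9a on chromosome 2, fell (-0.45 ± 0.14, SE, n = 2 each, adjusted p = 0.0333) and also passed adjusted over the list alone. The call of Scn3a ended without any 1 of the 4 libraries (highest adjusted p = 0.33). Of the 11 tested neighbours of Scn9a, Galnt3, an enzyme of mucin-type glycosylation, rose (0.43 ± 0.13, adjusted p = 0.0193) and Scn3a fell, with 1 higher and 2 lower adjusted over the list alone. Galnt3 lost its call without mCherry replicate 2 or either ZF-SCN9A replicate (highest adjusted p = 0.201), and also without a filter and with all 10 libraries. Both calls ended with the strand column, and that of Scn3a after the correction for exon length. DESeq2 called neither Scn3a nor Galnt3, and camera called neither list (adjusted p = 0.33 and adjusted p = 0.708). Fry's test of change in either direction passed for the neighbours (adjusted p = 0.0219) and 7 other lists, the smallest being the interferon list (adjusted p = 0.00671), so it does not set the neighbours apart.

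The last comparison set the change of each repressor from its own control against that of the other, gene by gene. The dCas9-empty libraries held reads of the dCas9 entries, while the mCherry libraries held only 35 and 14 reads of the ZF entry. Type of repressor, type of control, depth and arm therefore cannot be told apart in this difference. Git1 stood at 0.04 ± 0.05 with dCas9 and fell with the zinc finger, a difference (dCas9 minus ZF) of 1.52 (adjusted p = 2.23e-11). Differences of the same direction were found for Klhl7 (1.78), Ttbk1 (1.51), Adam15 (1.93), the microtubule polymerase Ckap5 (1.29) and the acyl-CoA synthetase Acsl1 (1.19), with adjusted p from 9.78e-11 to 2.50e-09. Ckap5 and Acsl1 fell with the zinc finger by 1.39 and 1.33 on the log2 scale. In the opposite direction stood heme oxygenase Hmox1 (-1.08, adjusted p = 4.97e-07), Mamdc2 (-1.27), the serotonin-gated channel subunit Htr3a (-0.88), the lysosomal trafficking regulator Lyst (-0.63), the semaphorin receptor Plxnd1 (-0.73) and the lipid-binding protein Stard5 (-0.86, 22% of its exon bases overlapped by Il16), all of which rose with the zinc finger. These 12 differences passed without each library in turn and with each other tool.

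The difference passed for 143 of 15766 genes, 102 higher and 41 lower in dCas9 minus ZF, against 1726 at an unadjusted p under 0.05. DESeq2 called 150, of which 126 were shared, and limma-voom 112. The count was 241 without dCas9-empty replicate 3, 79 without mCherry replicate 1, 71 without ZF-SCN9A replicate 1 and 83 without ZF-SCN9A replicate 2. Of 12833 genes tested in both comparisons, 2 were called in the same direction, Scn9a lower and 1600002K03Rik higher (1.17 ± 0.22 with the zinc finger, adjusted p = 1.43e-05, but adjusted p = 0.0830 by DESeq2), where independent lists would share 0.0279 and 0.0767. Scn9a is the target of both repressors and the only decrease called with dCas9. Its sharing therefore says nothing about effects on other genes. Without dCas9-SCN9A replicate 3 only Scn9a was shared, and without dCas9-SCN9A replicate 1 there were 4. Log2 fold changes of both comparisons had a Pearson correlation of 0.057 and a Spearman correlation of 0.067 across genes, which are not independent replicates. Among the 603 other genes called with the zinc finger, 58.9% had the same sign with dCas9. The share over all genes is not given here. Log2 fold changes fell with exon length in both comparisons, which alone can make signs agree.

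**Figure D4:**
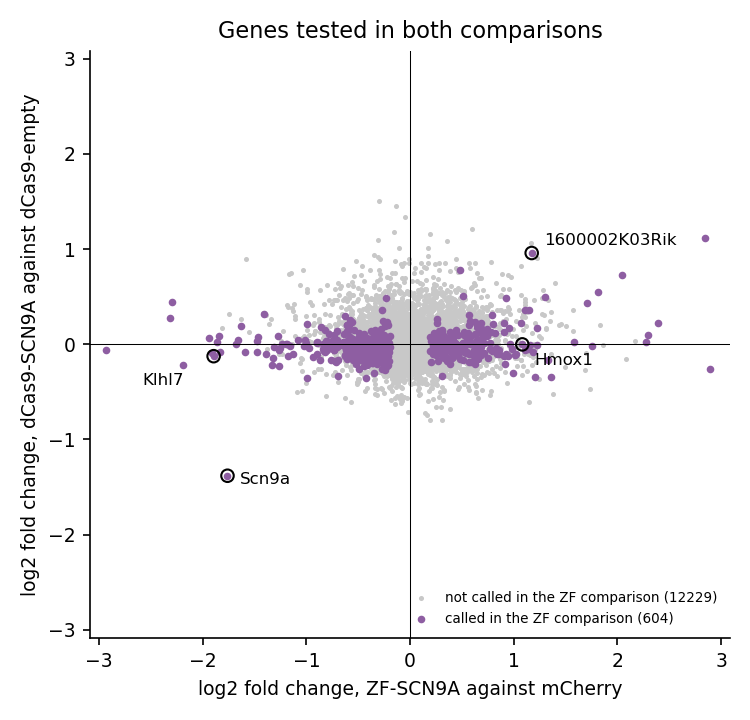
Log2 fold change with the zinc finger (x axis) against that with dCas9 (y axis) for the 12833 genes tested in both, with genes called in the ZF comparison coloured. Scn9a lies low on both axes, at -1.76 with the zinc finger and -1.38 with dCas9, while Klhl7 lies low on the ZF axis and near 0 on the dCas9 axis.

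**Figure D5:**
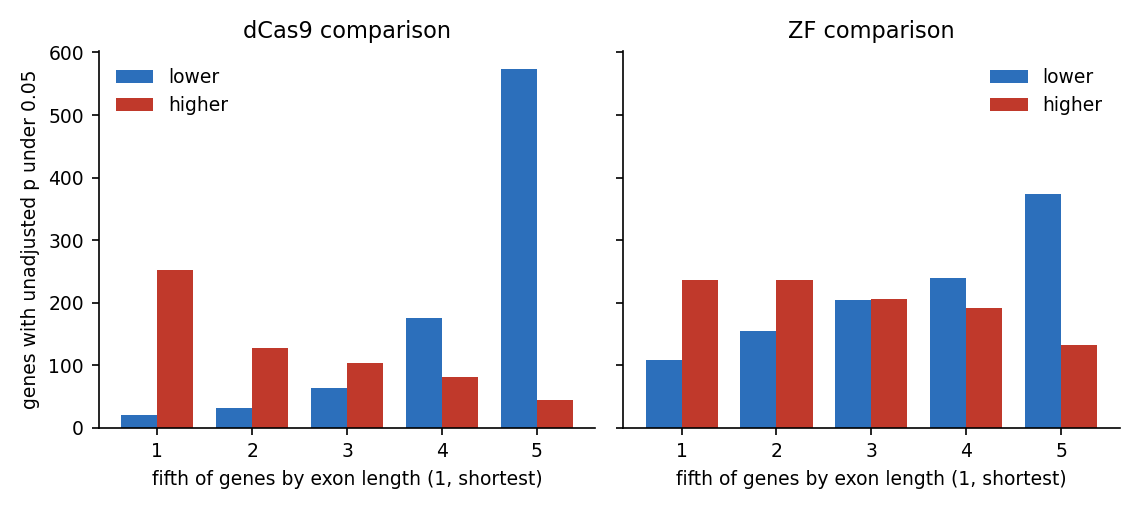
Number of genes lower (blue) and higher (red) at an unadjusted p under 0.05 (y axis) in 5 equal groups of genes by exon length (x axis, shortest first), for both comparisons. With dCas9 the longest group holds 574 lower and 44 higher genes, and with the zinc finger 374 and 133.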

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

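The test of a loss of Scn9a below was chosen only after its result had been seen.

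The results in this part are differences between the repressors that passed the test, and signals in entries of the count files that were not used in the tests. Among genes that fell with the zinc finger, the difference (dCas9 minus ZF, log2) was 2.01 for Colgalt2 (adjusted p = 0.0314), 1.93 for Adam15, 1.89 for Limd1, 1.83 for Slc50a1, 1.78 for Klhl7, 1.70 for Eif4e3, 1.56 for Sncg, 1.52 for Git1, 1.51 for Ttbk1, 1.40 for Tarsl2, 1.29 for Ckap5 and 1.19 for Acsl1. Among genes that rose with it, the difference was -1.27 for Mamdc2, -1.19 for Ankrd37, -1.08 for Hmox1, -0.88 for Htr3a, -0.86 for Stard5, -0.73 for Plxnd1, -0.63 for Lyst and -0.43 for Trib3. Snora17, which rose with dCas9, differed by 1.60 (adjusted p = 0.00756), and Slc39a7, called in neither comparison, by 1.45 (adjusted p = 0.0296).

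Genes at least 2-fold lower with the zinc finger numbered 36 besides Scn9a, with a median of -1.40 (quartiles -1.84 and -1.22). A trend with exon length or GC content could lower genes together. After correction for exon length or GC content the median was -1.44 or -1.40, with 36 of 36 still called, so the fitted trends account for little of these falls. For exon length the trend was itself small, with medians from 0.048 in the shortest group of genes to -0.035 in the longest. Correcting for it could not have undone decreases of this size. For GC content only the Spearman correlation across all genes is given (0.16), not the size of the trend. As the genes were chosen for large falls, neither correction is a test of what lowered these genes. Loss of Scn9a might lower them as well, but with dCas9, which also lowered Scn9a, their median was -0.0071 (quartiles -0.0878 and 0.0461) and 19 of 36 were negative. This argues against loss of Scn9a as the cause. Binding of the zinc finger at other sites and the difference between its plasmid and mCherry's were not tested and remain open.

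Plasmid entries were compared as reads scaled to 1 M gene counts. The dCCas9 entry stood at 7962 ± 733 in dCas9-empty and 11895 ± 956 in dCas9-SCN9A, and the dNCas9 entry at 4781 ± 199 and 3684 ± 324 (SD, n = 3 each). Their ratio was 1.66 ± 0.09 and 3.23 ± 0.02, so the dCas9 groups differ in their plasmid reads as well as in what is directed at SCN9A. The ZF entry stood at 39817 ± 894 in ZF-SCN9A and the mCherry entry at 28619 ± 481 in mCherry (SD, n = 2 each). Unmapped reads were 7.64% ± 0.37 of the listed reads in dCas9-SCN9A against 7.10% ± 0.10 in dCas9-empty, and 9.15% ± 0.26 in ZF-SCN9A against 7.18% ± 0.26 in mCherry. Multimapping reads were 8.88% ± 0.09 in dCas9-SCN9A against 8.21% ± 0.19 in dCas9-empty.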

How the results depend on the processing

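Corrections for exon length and GC content were chosen only after the data had been seen. The fall of Scn9a kept its direction and passed in every alternative, from -1.51 to -1.30 with dCas9 and from -1.92 to -1.65 with the zinc finger. The 12 genes named for a difference between the repressors kept their calls in all 216 fits. The cause was not tested for any of the following changes. Some settings differ by design: leaving out libraries leaves fewer samples, and a 2-fold minimum is a stricter rule. The strand column held about 50% of the reads of both strand columns, so that setting also has a lower depth. In the dCas9 comparison (6 genes called) the count was 172 without a filter (56 higher, 116 lower), 69 with DESeq2 (2 and 67), 13 with the strand column (7 and 6), 29 with all 10 libraries (7 and 22), 3 with a 2-fold minimum and 2 after the correction for exon length. Without single libraries it was 7, 3 and 21 (dCas9-empty replicates 1 to 3) and 34, 17 and 1 (dCas9-SCN9A replicates 1 to 3). In the ZF comparison (609) it was 115 with DESeq2, 283 with the strand column, 348 with all 10 libraries and 70 with a 2-fold minimum. It was 262 and 787 without mCherry replicate 1 and 2, and 201 and 249 without ZF-SCN9A replicate 1 and 2. For the difference between the repressors (143) it was 274 without a filter, 241 without dCas9-empty replicate 3, 79 without mCherry replicate 1, and 71 and 83 without ZF-SCN9A replicate 1 and 2. Genes called in both comparisons (2) were 11 without a filter, 1 with a 2-fold minimum, 4 without dCas9-SCN9A replicate 1 and 1 without dCas9-SCN9A replicate 3. Gene lists called with dCas9 (1) were 6 without a filter and 0 with camera's estimated correlation or fry's directional test. Without single libraries they were 4, 5 and 3 (dCas9-empty) and 3, 6 and 2 (dCas9-SCN9A). With the zinc finger 4 lists were called, against 0 with camera's estimated correlation or fry's directional test. Fry's test of change in either direction passed for 8 lists with the zinc finger and 1 with dCas9, none of them called by camera. The hypoxia and glycolysis list reversed to a median of -0.012 without mCherry replicate 1 and stood at 0.25 without mCherry replicate 2. Samples share a replicate number that the labels do not explain. With that number as a replicate block the count was 262 with dCas9 (84 higher, 178 lower), 569 with the zinc finger, 429 for the difference, 21 in both and 2 lists with dCas9. Samples of the same number deviated together with correlations of 0.238, 0.161 and 0.0397 in the dCas9 arm. Each dCas9-SCN9A library correlated best with the dCas9-empty library of its own number, though dCas9-empty replicate 3 correlated best with dCas9-SCN9A replicate 2 (0.101). Whether the numbers pair the samples stays open, and with it the count of calls with dCas9. Among named genes, 181 of 243 alternative results with dCas9 and 872 of 1151 with the zinc finger kept their direction and side of the threshold, and 0 reversed. Of 74 named genes called with the zinc finger, 23 stayed called without each library. The ZF arm, at 4.41 M to 7.48 M gene counts, recovered 24% of the smallest simulated changes against 56% in the dCas9 arm, which also had more libraries.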

Other observations

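Several tests in this part were chosen after values had been seen: the corrections for exon length and GC content, and the second condition set on the shared effect below.

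Beyond the lists that passed, the zinc finger changed single genes of several programmes. Stat2, a transcription factor of interferon signalling, fell from 98.1 to 39.5 CPM (-1.31, adjusted p = 3.05e-33, n = 2 each), and Trim25, a ubiquitin ligase of antiviral sensing, also fell (-0.43, adjusted p = 1.02e-05). The interferon list held 2 higher and 4 lower genes (camera adjusted p = 0.318). Egr1, an immediate early transcription factor, fell from 82.5 to 47.9 CPM (-0.78, adjusted p = 2.15e-11), in a list with 3 lower genes (camera adjusted p = 0.649). Gata2, a factor of sympathoadrenal identity, fell from 281 to 189 CPM (-0.58, adjusted p = 5.11e-14), in a list with 2 higher and 3 lower genes (camera adjusted p = 0.491). The potassium and calcium channel list held 2 higher and 2 lower genes (camera adjusted p = 0.318). Hmox1 rose from 91.3 to 194 CPM (1.08, adjusted p = 5.00e-39), while the NRF2 target list held 2 higher and 1 lower gene (camera adjusted p = 0.318). Acta2, smooth muscle actin, rose from 14.9 to 26.8 CPM (0.86, adjusted p = 2.99e-05), 1 of 2 higher fibroblast markers among 7 (camera adjusted p = 0.491). The 6 named genes stayed called without each library, but the call of Acta2 ended with the strand column (0.51, adjusted p = 0.281) and with DESeq2 (adjusted p = 0.0879).

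The remaining lists of the ZF comparison did not pass camera. Mitosis genes were positive in 22 of 25 cases with 1 called higher and 1 lower (adjusted p = 0.0715). Neuronal structure held 1 higher and 1 lower gene, NF-kB targets and pain and opioid genes 1 higher each, and TRIM28 and its partners 1 lower (adjusted p = 0.318, 0.327, 0.318 and 0.318). Heat shock and mitochondrially encoded genes held 1 lower each (adjusted p = 0.491 and 0.645). None was called among endoplasmic reticulum stress (20 tested), p53 targets (16), DNA replication (26), nuclear-encoded respiratory chain subunits (30), histones (8), lysosome and autophagy (25), glia (4), and immune and endothelial markers (4), with adjusted p of 0.708, 0.933, 0.604, 0.318, 0.812, 0.883, 0.933 and 0.318. At an unadjusted p under 0.05 these lists held 0, 0, 4, 4, 0, 2, 0 and 0 genes, DESeq2 called 0 (with no adjusted p for 6 histone, 2 immune and endothelial, and 1 p53 target genes), and limma-voom called 1 lysosome gene. The median, mean and camera direction differed in sign for the immediate early, sympathoadrenal, NRF2, fibroblast and endoplasmic reticulum stress lists.

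Gm2314 stood at 7.57, 1.86 and 6.15 CPM in dCas9-SCN9A and at 0 in each dCas9-empty library. Reads on the ZF entry numbered 35 and 14 in mCherry replicates 1 and 2, and reads on the mCherry entry 59 and 11 in ZF-SCN9A, 7 in dCas9-empty replicate 1 and 9 in dCas9-SCN9A replicate 1.

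DESeq2 called 66 genes lower with dCas9 besides Scn9a, with a median of -0.246 (quartiles -0.277 and -0.213). A trend with exon length may account for part of this: the median was -0.156 after correction (quartiles -0.188 and -0.116), which leaves it open, while the GC correction (-0.236) argues against GC content. An effect that both repressors share could lower the same genes, and with the zinc finger their median was -0.108 (55 of 66 negative), which met the condition written beforehand. After that result was seen, the exon length correction was also asked for, and the median was then -0.038 (38 of 66 negative). The shared effect is therefore left open.

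The higher values of the mitochondrially encoded messenger RNAs with dCas9 had a median of 0.335 (quartiles 0.265 and 0.580). It might come from the trend with exon length, with 0.187 after correction, or from dCas9-empty replicate 1 with its low share, with 0.189 without it. Both values lie between what each cause and its absence predicted, so both stay open. Counts of calls were also compared with other divisions of the same libraries into equal groups. The real division gave 6 genes with dCas9 (highest other 0), as many as in 1 of 10 divisions, and 609 with the zinc finger (highest other 0), 1 of 3. For lists with dCas9 the real division gave 1 and others up to 9, at least as many in 10 of 10, so these libraries hold shared structure unrelated to the groups. With the zinc finger the real division gave 4 lists and the others 3 and 1. Too few divisions exist for a share under 0.05.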
